A study of Mus musculus with 42 samples.

How the data were processed

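RNA of kidney and liver was sequenced by CEL-seq, a method that barcodes each sample and reads the 3' ends of polyadenylated RNA, in 30 kidney and 12 liver libraries of 10 groups. The values used were counts per gene in a table of 43629 Ensembl genes and 42 libraries, as deposited by the authors. The submitters' processing notes name bcl2fastq 1.8.4, Trimmomatic 0.32, STAR 2.5.2b and featureCounts 1.5 and the mm10 mouse genome. The annotation release, the strand setting and whether molecular identifiers were collapsed are not given in the sources used here. Where genes overlap or have near-identical copies, counting may split reads between them, and such genes are named as uncertain where their values are given. Of the genes, 42548 were matched to GENCODE M21 (GRCm38) for symbols and coordinates, 1081 had no symbol and 56 shared a symbol with another gene. All columns of the table were matched to samples by name, with 0 left unused.

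Libraries were grouped by the tissue and compound in their labels. In kidney each compound was compared with control, and AZD8055 with KU0063794; in liver the 3 compounds were compared with each other. An F test for any difference was run in each tissue, and an F test of the compound by tissue interaction was run on the 24 libraries of the compounds given in both. Counts were scaled by TMM and filtered by filterByExpr, which left 11719 genes in kidney, 9490 in liver and 12262 for the interaction. All libraries of a tissue entered 1 fit of edgeR's quasi-likelihood model (edgeR 4.0.16, R 4.3.3), with Benjamini-Hochberg adjustment and a threshold of 0.05. The biological coefficient of variation was 0.294 in kidney and 0.191 in liver. Levels are TMM-normalised CPM, except in the check of the tissue labels, which used the raw totals. TMM, RLE and DESeq2 scaling each left the median log2 change of all genes within 0.1 of 0 in the comparisons of 2 groups.

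Gene lists, 41 of pathways and 26 of cell types, were tested by camera (limma 3.58.1) with the correlation between genes estimated from the data, over the lists with at least 5 measured members, 62 in kidney and 53 in liver. The comparisons, tests, lists, the rule for named genes and the other methods, from DESeq2 to fry, were fixed before the data were examined. The rule took, in each comparison of 2 groups, the 12 genes with the largest change in each direction among those past 0.05 with a mean of at least 5 CPM and all libraries of the compound on the same side of the other group's mean. Where fewer than 5 genes passed, it took those and the next by p up to 5, and it added up to 2 passing members of each list (4 where the list passed), genes lower or higher under at least 4 compounds, the 10 smallest p of the interaction and of each F test, and 4 tissue markers. The genes named in the text are a subset of the rule's genes, picked after their values were seen. Apoh, Gm5617, Malat1 and Kap fall outside the rule and were also picked then, and Gm10800 and Cyp4a12b are named without a level. Some genes that the rule took are not reported here.

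Each result was also computed with DESeq2 1.42.0, RLE scaling, no filter, limma voom with sample weights, a fit of the 2 groups alone, the replicate number as a block, leaving out each library in turn, and lists were also tested by camera with a preset correlation, camera with the block and fry. Added after the data were seen were a covariate for the log2 share of satellite-like counts, leaving out the kidney libraries at or above 5% of such counts, leaving AZD8055 replicate 4 out of the kidney comparisons that do not include it, leaving out each kidney library for the similarity of compounds, and a covariate for the earlier or later part of the kidney columns in file order. Satellite-like gene models were 13 models that share at least 5% of their 24-base words with Gm10800 on either strand. For the similarity of compounds, 100 sets of unchanged groups were simulated with the controls drawn as well, so that their sampling error is shared between the groups, and the 6 controls were split into groups of 3 in all 10 ways. Regroupings of the libraries were limited to 50 because of the time a fit takes, a limit set before any result of them was seen.

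Libraries were compared for duplicates by a chi-square per gene. The lowest value was 4.10, between controls 1 and 4, so each library counted as a sample. On simulated counts with 200 changed genes, edgeR recovered 48% of 2-fold and 87% of 4-fold changes for AS-703026 in kidney (11444 genes; 2.17% of calls false), 46% and 89% for enzastaurin in kidney (11425 genes; 3.57%), 61% and 98% for AS-703026 against enzastaurin in liver (9342 genes; 5.36%), and 23% and 57% for the interaction (11915 genes; 2.44%). These counts were drawn for each gene independently, without outlying libraries or differences in the satellite-like share. The shares recovered and false therefore hold for such counts and were not measured for the real libraries. Shallow libraries limit the precision of low genes, and transcripts under about 3 counts per library were given as means with no fold. Shares of counts in single libraries have Wilson intervals at a level of 95%. Liver controls were not analysed here.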

Results

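Gene expression was measured in kidney and liver of male UM-HET3 mice, a genetically mixed stock bred from 4 inbred strains, that had eaten a diet with 1 of 6 compounds for 1 month. The diets began at 3 months of age and tissue was taken at 4 months. The series describes the compounds as predicted to lengthen life, and the comparisons ask how each changed the transcripts of an organ. Kidney was given for AS-703026 at 30 ppm, ascorbyl-palmitate at 6.3 ppm, AZD8055 at 20 ppm, enzastaurin at 75 ppm, GDC-0941 at 50 ppm and KU0063794 at 10 ppm, with 4 libraries for each compound and 6 from control littermates. Liver was given for AS-703026, enzastaurin and GDC-0941, with 4 libraries each. Liver controls were not analysed here, so liver compounds were compared with each other. The submitters call the libraries biological replicates. Total gene counts ran from 863605 to 5691067 in kidney (median 2248550) and from 1084591 to 4361115 in liver (median 2792768).

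The tissue labels held in all 42 libraries by marker levels. Umod, the uromodulin of the thick ascending limb, lay between 542 and 4739 CPM (counts scaled to a common library total) in kidney libraries, and Slc34a1, the phosphate transporter of the proximal tubule, between 1873 and 8191. In liver, Slc34a1 reached at most 0.73 CPM, while Alb, which encodes serum albumin, lay between 7473 and 27841 and Apoa2, an apolipoprotein, between 7893 and 11991. Liver transcripts were also seen in 2 kidney libraries, with Alb at 640 CPM in enzastaurin replicate 1 and 211 CPM in AZD8055 replicate 4. Satellite-like gene models, a group of 13 around Gm10800, took from 0.0350% (Wilson 95% interval 0.0332% to 0.0370%) of the counts in enzastaurin kidney replicate 2 to 29.0% (28.9% to 29.1%) in AS-703026 kidney replicate 2. Such intervals, and the floor of 3 counts used for absent transcripts, cover counting error only. In liver their share was 0.857% (0.846% to 0.868%) or more in the AS-703026 libraries and 0.645% (0.636% to 0.654%) or less in the others. The log2 share went with the first principal component, the axis of largest variation between libraries. In kidney that axis held 24.2% of the variance and the correlation was 0.926. In liver it held 24.5% and the correlation was -0.801, where the sign of a component is arbitrary.

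**Figure D1:**
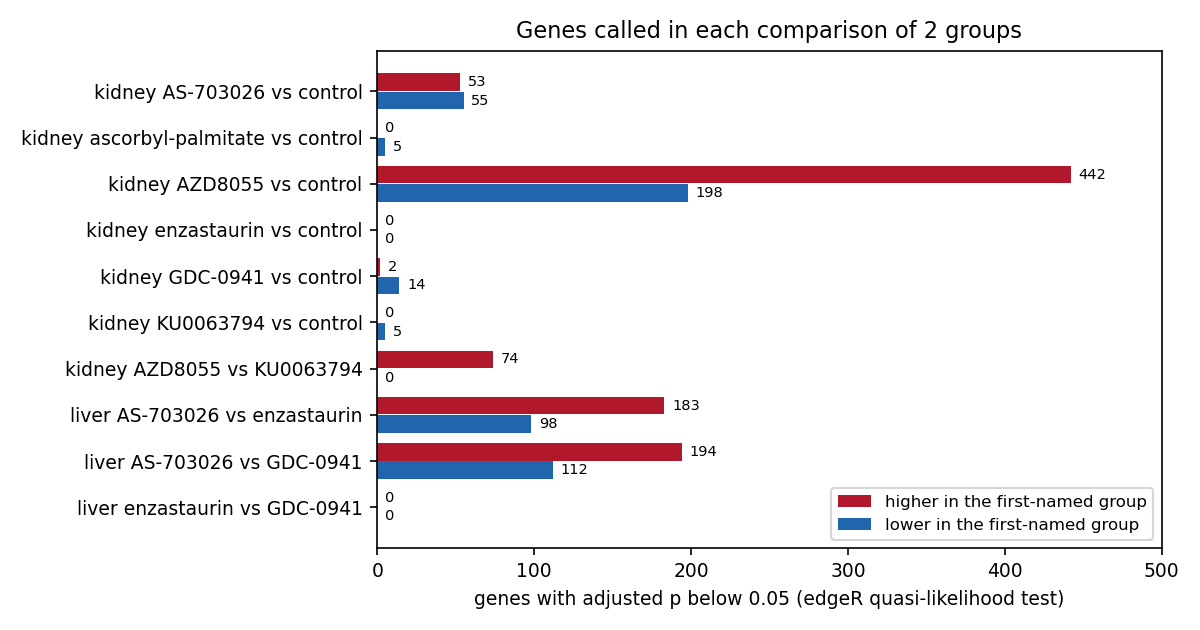
Number of genes past an adjusted p of 0.05 by edgeR's quasi-likelihood test in each comparison of 2 groups, with 1 bar for genes higher (red) and 1 for genes lower (blue) in the group named first. AZD8055 against control in kidney had 442 genes higher and 198 lower, and enzastaurin against control had 0.

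In kidneys of mice given AS-703026, an inhibitor of the kinase MEK also known as pimasertib, the vitamin D-inactivating enzyme gene Cyp24a1 and the injury marker gene Havcr1 were higher, and 4 androgen-responsive genes were lower. Cyp24a1, the enzyme that inactivates the vitamin D hormone, rose from 53.1 ± 19.8 CPM (SD, n = 6) in control to 215 ± 96.0 CPM (SD, n = 4), a log2 change of 2.01 ± 0.41 (SE). Havcr1, which encodes the injury marker KIM-1, rose from 4.76 ± 3.79 to 42.3 ± 28.9 CPM, a log2 change of 3.24 ± 0.66. Slco1a1, an organic anion transporter of the proximal tubule, fell from 699 ± 217 to 219 ± 32.2 CPM, a log2 change of -1.67 ± 0.31. Their adjusted p-values were 0.0241, 0.0243 and 0.0203 by edgeR's quasi-likelihood test. Each held its direction in 4 of 4 AS-703026 libraries against the control mean. As the naming rule requires this of genes taken for their largest change, it is no separate support. None of these calls held without AS-703026 replicate 4, control 4 or control 5. Cyp24a1 is ENSMUSG00000038567 (GRCm38 chromosome 2, 170482708 to 170497145), Havcr1 is ENSMUSG00000040405 (chromosome 11, 46735080 to 46779578) and Slco1a1 is ENSMUSG00000041698 (chromosome 6, 141907282 to 141946962). Cyp4a10, a fatty acid hydroxylase, rose by 1.59 on the log2 scale.

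Of 14 measured androgen-responsive genes of the male mouse kidney, 4 fell in AS-703026 kidney and 0 rose, and 9 were lower and 2 higher when adjusted over the list alone. These 4 were Slco1a1, Cyp4a12a, which makes 20-HETE and fell from 1778 ± 278 to 791 ± 158 CPM, Odc1, the ornithine decarboxylase of polyamine synthesis (log2 change -1.63), and Slc22a30, a predicted organic anion transporter (log2 change -1.32). Reads of Cyp4a12a may be shared with its close copy Cyp4a12b, so its level is uncertain. The median log2 change of the list was -0.88, and the list test gave adjusted p = 0.290 with an estimated correlation. Esm1, a secreted proteoglycan of endothelial cells, fell by 1.62 on the log2 scale. Cycs, which encodes cytochrome c, fell by 0.57, while Cldn16, a claudin of the thick ascending limb, rose by 1.76.

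Some markers of the collecting duct and of the thin limb and inner medulla were called higher with AS-703026. No call of this comparison held without replicate 4, and the changes of Cryab, Aqp2 and Aqp4 were also smaller without it. Of 8 measured thin limb and inner medulla genes, 4 rose (5 adjusted over the list alone), with a list median of 2.18 (adjusted p = 0.290 with an estimated correlation). Of 11 principal cell genes, 3 rose (5 adjusted over the list alone), with a median of 0.55 (adjusted p = 0.385 with an estimated correlation). Among them Cryab, a small heat shock protein abundant in the inner medulla, had a log2 change of 3.92, Aqp2, the vasopressin-regulated water channel, 2.69, and Aqp4, another water channel, 3.58. Cryab stood at 2750 CPM in replicate 4 and at no more than 368 in the other 3 AS-703026 libraries, and Aqp2 at 1333 and no more than 150. Without replicate 4 the log2 change was 1.92 for Cryab, 1.00 for Aqp2 and 2.06 for Aqp4, and none passed 0.05 (edgeR adjusted p of 0.224, 0.232 and 0.352). Krt18, a keratin of simple epithelia, Gstm2, a glutathione transferase, and Ifit3, an interferon-induced gene, had changes of 2.62, 1.69 and 2.55, which became 0.54, 0.47 and 0.55 without that library. Of the 12 kidney injury genes measured 2 rose, Havcr1 and Krt18 (4 adjusted over the list alone; adjusted p = 0.290 with an estimated correlation). None of the 14 measured ERK feedback genes, which report signalling below MEK, passed 0.05 (median -0.29, adjusted p = 0.385 with an estimated correlation).

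In all, 53 genes were higher and 55 lower in AS-703026 kidney among 11719 tested by edgeR (1772 at an unadjusted p under 0.05). The count was 0 without AS-703026 replicate 4, control 4 or control 5, 11 without control 3, 42 without control 1, 67 without AS-703026 replicate 2, 176 without replicate 1, 244 without control 2 and 339 without AZD8055 replicate 4, which shares the fit. Satellite-like shares of 5% or more occurred in 3 of the 4 AS-703026 kidney libraries. Leaving out the 11 kidney libraries at that level left 1 AS-703026 library and 1 gene called, so it says little about any gene. With the satellite-like share as a covariate the change of Cyp24a1 was 1.99 (edgeR adjusted p = 0.0411), and it was 2.27, 2.02 and 1.98 without AS-703026 replicate 4, control 4 or control 5, where its adjusted p was 0.0793, 0.0706 and 0.0798. Camera called 0 of 62 gene lists (8 at an unadjusted p under 0.05, 23 by camera with a preset correlation, 0 by fry).

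**Figure D2:**
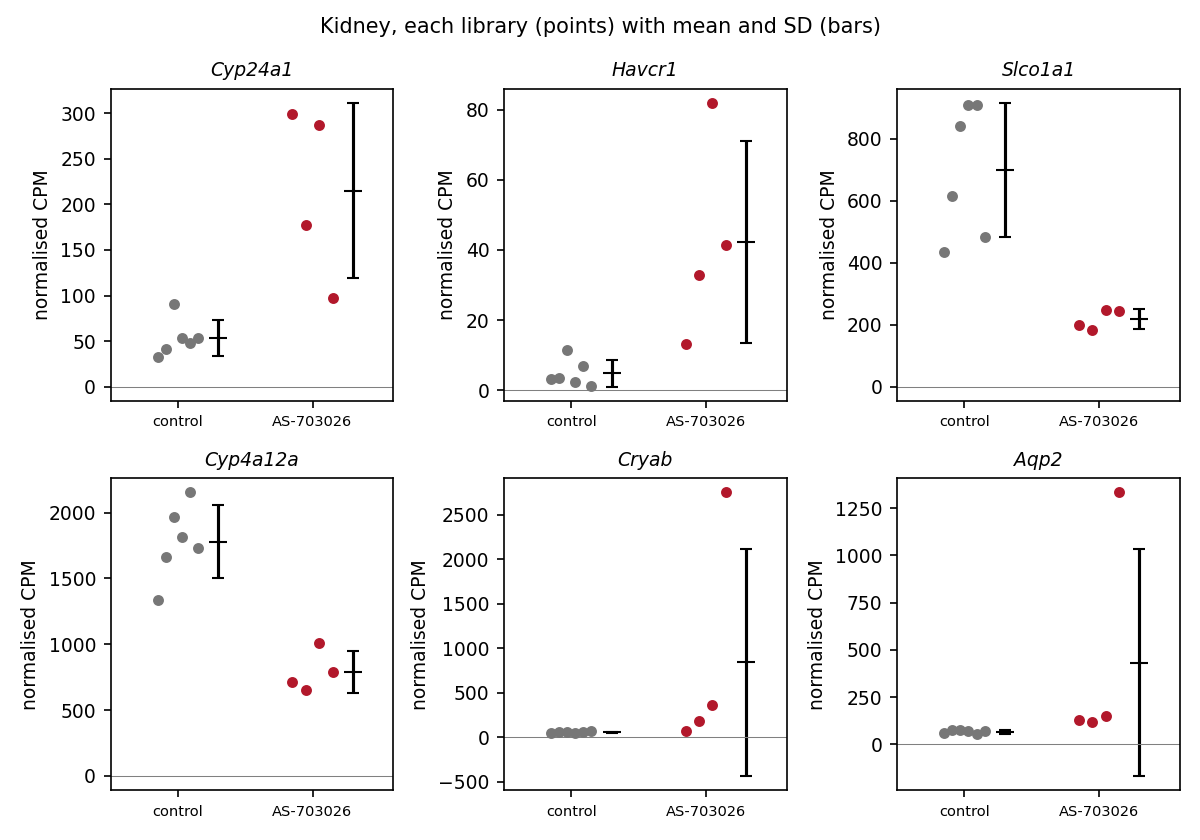
Normalised CPM of 6 genes in the 6 control and 4 AS-703026 kidney libraries, 1 point per library, with the mean and SD of each group beside the points. Cyp24a1 lay between 96.8 and 299 CPM in the AS-703026 libraries and between 32.9 and 90.4 in control, and Cryab reached 2750 in 1 AS-703026 library.

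AZD8055, an inhibitor of the kinase mTOR, was the kidney comparison with the most calls, and most of the calls of higher genes, adipocyte genes among them, rested on a single library. Ucp1, the uncoupling protein of brown fat, had a mean of 1040 CPM against 3.50 ± 2.26 (SD, n = 6) in control and Fabp4, the fatty acid carrier of adipocytes, 4390 CPM against 74.0 ± 18.8. In replicate 4 these genes stood at 4140 and 17334 CPM, and in the next highest AZD8055 library at 9.06 and 107 CPM. All 8 measured adipocyte genes were higher (8 adjusted over the list alone, median log2 change 6.60, adjusted p = 0.501 with an estimated correlation). Without replicate 4 the log2 changes of Ucp1 and Fabp4 went from 8.32 and 5.89 to 1.00 and 0.01, and those of Thrsp, Fasn and Pdk4, genes of lipid synthesis and fuel choice, from 7.42, 5.83 and 5.16 to -0.13, -0.36 and -1.34, with none past 0.05.

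The calls of the mitochondrial genes named here also rested on that library. Of 30 PPAR alpha and fatty acid oxidation genes 15 rose (21 adjusted over the list alone), of 23 tricarboxylic acid cycle genes 13 (20), of 72 nuclear genes of oxidative phosphorylation 17 (35 higher and 1 lower), of 17 fatty acid synthesis genes 12 (15 higher and 1 lower), of 14 glycolysis genes 5 (7) and of 70 mitochondrial ribosome genes 8 (11), each with adjusted p = 0.501 with an estimated correlation. Hadha, a subunit of the trifunctional protein of beta oxidation, had a log2 change of 2.12, Sucla2 of the tricarboxylic acid cycle 1.18, and Ldha, the lactate dehydrogenase subunit, 0.70. These were 0.43, 0.33 and 0.34 without replicate 4. Uqcrc2 and Ndufb9 of oxidative phosphorylation and Mrpl10 of the mitochondrial ribosome went from 0.69, 0.67 and 0.77 to 0.46, 0.45 and 0.49, and none of these 6 genes passed 0.05 without that library. Eif4ebp1, the translation repressor controlled by mTOR, went from 2.91 to 0.27, and Map1lc3a, an autophagosome protein, from 0.86 to 0.47 (edgeR adjusted p of 0.804 and 0.116 without it). Of 63 cytosolic ribosomal protein genes 1 rose, Rps4x (1 adjusted over the list alone, adjusted p = 0.826 with an estimated correlation), and of 40 autophagy and lysosome genes 4 did (4 adjusted over the list alone, adjusted p = 0.826).

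The call of Hpd did not rest on that library. Hpd, which encodes 4-hydroxyphenylpyruvate dioxygenase of tyrosine breakdown (ENSMUSG00000029445, GRCm38 chromosome 5, 123171807 to 123182727), stood at 39.1 ± 6.22 CPM in control (SD, n = 6) and rose by a log2 change of 1.29 ± 0.25 with an edgeR adjusted p of 0.00389, and stood at 97.1 to 140 CPM in replicates 1 to 3 and at 39.6 in replicate 4. Without replicate 4 its change was 1.54 ± 0.22 and its adjusted p 8.86e-04, whereas without the 11 libraries of high satellite-like share, AZD8055 replicates 1 and 2 among them, it was 0.86 with an adjusted p of 0.136. Neat1, a nuclear long noncoding RNA, fell from 835 ± 554 to 204 ± 121 CPM, and Slc12a3, the thiazide-sensitive sodium chloride transporter, from 114 ± 21.9 to 50.3 ± 29.3 CPM. Without replicate 4 Neat1 kept its call (log2 change -2.54, edgeR adjusted p = 0.0361) and Slc12a3 did not (-0.86, 0.218). Neat1 lost its call without the libraries of high satellite-like share. In controls 2 and 6 it stood at 204 and 292 CPM, against 523 or more in the other controls.

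AZD8055 kidney had 442 genes higher and 198 lower by edgeR (2340 at an unadjusted p under 0.05). Without AZD8055 replicate 4 the counts were 3 higher and 22 lower, of which 24 were among the 640. The 3 higher were Hpd, Apoh, a plasma apolipoprotein, and the predicted gene Gm5617, named here after their values were seen. Hpd and Apoh are also liver genes, and the median of the hepatocyte list stood 0.44, 0.53, 0.30 and 3.45 above the control mean in AZD8055 replicates 1 to 4. Without control 3, 4 or 5 the total was 353, 312 or 308. Camera called 0 of 62 lists (4 at an unadjusted p under 0.05, 18 with a preset correlation, 2 by fry).

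**Figure D3:**
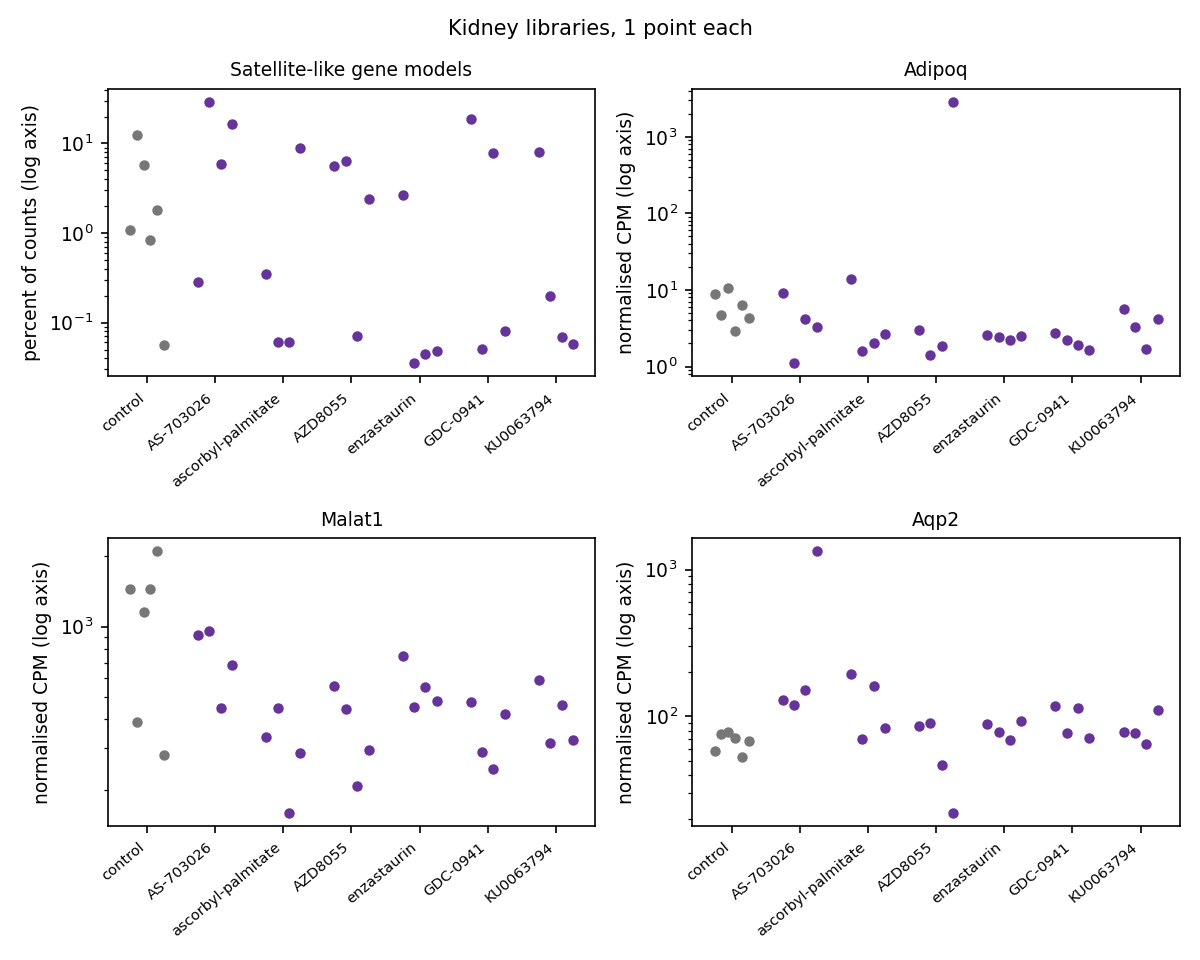
Library measures in kidney on log axes, 1 point per library by group: the percent of counts on satellite-like gene models, and normalised CPM of Adipoq, Malat1 and Aqp2. Adipoq stood at 2843 CPM in AZD8055 replicate 4 and at no more than 13.8 in the other kidney libraries, and Malat1 was 391 and 282 CPM in controls 2 and 6 and from 1159 to 2101 in the other 4 controls.

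The remaining 4 compounds gave few calls in kidney, mostly of lower genes, and some of these were lower under several compounds. Cpsf6, a subunit of the factor that cleaves the 3' ends of messenger RNA, fell from 111 ± 35.2 CPM (SD, n = 6) in control to 57.0 ± 4.86 with ascorbyl-palmitate, 57.9 ± 8.05 with GDC-0941 and 55.7 ± 3.31 with KU0063794 (SD, n = 4 each). Khdc4, a splicing regulator, fell from 88.4 ± 32.7 to 39.5 ± 9.17, 39.2 ± 6.01 and 36.9 ± 4.01 CPM in the same 3 groups. Both also fell with AS-703026 (log2 changes -0.91 and -0.94) and AZD8055 (-0.86 and -1.20). Both were lower than the control mean in 4 of 4 libraries of each compound, which the naming rule requires of genes taken for their largest change. With enzastaurin, an inhibitor of protein kinase C, the log2 changes of Cpsf6 and Khdc4 were -0.76 and -0.99 with an edgeR adjusted p of 0.146, which does not pass. Zfp697, a zinc finger gene, fell with AS-703026, ascorbyl-palmitate, AZD8055 and GDC-0941 (log2 changes -1.41, -1.39, -1.35 and -1.21), and its values were -0.76 with KU0063794 and -0.89 with enzastaurin, where it did not pass. The unnamed gene ENSMUSG00000089788 fell with 5 compounds, by 2.26 on the log2 scale with KU0063794.

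With ascorbyl-palmitate, a fat-soluble ester of vitamin C, 5 genes were called lower than control and 0 higher by edgeR (1467 at an unadjusted p under 0.05), the 4th named here being Wsb1, part of a ubiquitin ligase, with a log2 change of -1.73 ± 0.33 and an edgeR adjusted p of 0.0405. GDC-0941, a PI3K inhibitor also known as pictilisib, had 2 genes higher and 14 lower (1532 at an unadjusted p under 0.05). Rcl1, a ribosomal RNA processing factor, rose from 4.71 ± 1.23 to 13.4 ± 1.57 CPM, and Sfpq, a splicing factor, and Xpo1, the nuclear exporter, fell by 0.90 and 0.94 on the log2 scale (edgeR adjusted p = 0.0390 for each). Ube3a, Med13, Zfp24 and Crebzf, genes of ubiquitin transfer and transcription, fell with adjusted p = 0.0485. With KU0063794, an inhibitor of mTOR, 5 genes were called lower and 0 higher (1143 at an unadjusted p under 0.05), with Ice2, a factor for small nuclear RNA transcription, at -1.13 and Stk35, a kinase, at -1.05. Enzastaurin gave 0 calls by edgeR (915 at an unadjusted p under 0.05), 27 by DESeq2 and 154 by limma voom, the lowest edgeR adjusted p being 0.146, with Ergic2 and Crem at -0.88 each.

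These small counts turned on single libraries. Without control 1, 3, 4 or 5 the counts for ascorbyl-palmitate, GDC-0941 and KU0063794 were 0. Without control 2 they were 130, 159 and 73, and without control 6 they were 86, 101 and 52, with 60 and 18 for enzastaurin. Leaving out a library of the compound itself gave 0, except 30 without ascorbyl-palmitate replicate 2 and 1 without GDC-0941 replicate 1, and GDC-0941 had 35 without AZD8055 replicate 4. Gene lists past 0.05 by camera numbered 0 of 62 for each of the 4 compounds, against 1, 2, 0 and 3 at an unadjusted p under 0.05 for ascorbyl-palmitate, GDC-0941, KU0063794 and enzastaurin, 14, 9, 10 and 11 by camera with a preset correlation and 0 by fry. Of the cytosolic ribosomal protein genes, 0 passed with KU0063794 (0 adjusted over the list alone) and 0 with GDC-0941 (4 adjusted over the list alone), and of 24 FoxO and insulin-responsive genes 0 passed with GDC-0941 (1 higher and 1 lower adjusted over the list alone, median -0.26, adjusted p = 0.861 with an estimated correlation).

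Across compounds, 28 genes were lower than control under 2 or more compounds and 2 were higher, and 4 were lower under 4 or more. The 6 comparisons share the control libraries. The correlation of log2 changes across the 11719 genes, which are not independent replicates, had a median of 0.336 over the 15 pairs of compounds (range -0.09 to 0.740, highest for ascorbyl-palmitate with GDC-0941). Unchanged groups simulated against such controls gave 0.424. The median covariance was 0.116 against 0.0916 simulated, a difference of 0.0243 with a range of -0.128 to 0.116, and 9 of 15 pairs lay above the simulated value. These counts were simulated for each gene independently, without deviations that genes share within a library. The simulated values are therefore no full measure for the real pairs, and no conclusion is drawn from the 9 pairs. With the controls split so that each compound met its own 3, the median correlation was 0.0939, and over genes of at least 20 CPM, for which no simulation was run, it was 0.526. AS-703026 and AZD8055 shared 24 lower genes, an overlap for which no value under shared controls was computed. The correlation of this pair was 0.347 against 0.403 simulated, and its covariance 0.140 against 0.0911. An F test for any difference among the 7 kidney groups called 294 genes by edgeR, and 140 without AZD8055 replicate 4, 147, 166 and 183 without control 5, 4 or 3, and 183 without AS-703026 replicate 4.

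AZD8055 and KU0063794 both inhibit mTOR, but their doses differed, 20 against 10 ppm. Directly compared, 74 genes were higher with AZD8055 and 0 lower by edgeR (1219 at an unadjusted p under 0.05; 23 by DESeq2, 0 by limma voom). Ucp1, Cidea, a lipid droplet protein, Cfd, the adipocyte protease adipsin, and Car3, a carbonic anhydrase of fat and muscle, led with log2 differences of 8.27, 7.37, 6.91 and 7.01, and all 8 adipocyte genes passed (8 adjusted over the list alone, adjusted p = 0.491 with an estimated correlation). The count was 0 without AZD8055 replicate 4 or without any KU0063794 library, and 296, 274 and 254 without AZD8055 replicate 1, 2 or 3. Fasn, the fatty acid synthase, differed by 5.90 with replicate 4 and by -0.30 without it. Camera called 0 of 62 lists (3 at an unadjusted p under 0.05, 21 with a preset correlation, 0 by fry).

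In liver, mice given AS-703026 had higher acute phase transcripts than mice given either other compound. Fgl1, a secreted liver protein induced by interleukin-6, stood at 3116 ± 1312 CPM (SD, n = 4) with AS-703026, 159 ± 63.6 with enzastaurin and 115 ± 25.9 with GDC-0941, log2 differences of 4.30 ± 0.36 and 4.76 ± 0.37 with edgeR adjusted p of 6.80e-05 and 2.34e-05. Saa1, serum amyloid A, stood at 8477 ± 9584 CPM against 56.0 ± 11.2 and 44.8 ± 9.25, log2 differences of 7.25 ± 0.96 and 7.57 ± 0.97 (edgeR adjusted p of 0.00155 and 9.38e-04). Reads of Saa1 and Saa2 may be shared, so each level is uncertain while both were higher. Lcn2, the siderophore-binding lipocalin, differed by 7.48 and 8.13, Orm2, an acid glycoprotein, by 6.46 and 6.82, and Hpx, the haem carrier hemopexin, by 2.15 and 2.26. Each of these genes was higher in 4 of 4 AS-703026 libraries. The naming rule requires this of genes taken for their largest change, so it is no separate support. Fgl1 is ENSMUSG00000031594 (GRCm38 chromosome 8, 41191434 to 41215156) and Saa1 is ENSMUSG00000074115 (chromosome 7, 46740497 to 46742980).

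Of 25 measured acute phase genes, 22 were higher against each compound (25 adjusted over the list alone in both), with medians of 2.14 and 2.26 and list p-values of adjusted p = 0.0708 and 0.0549 with an estimated correlation, which do not pass. The size varied between the AS-703026 libraries, with list medians of 2.94, 0.80, 2.53 and 1.57 above the mean of the other livers, whose own libraries lay between -0.16 and 0.20. Of 29 complement and coagulation genes, 8 were higher than with enzastaurin (11 higher and 2 lower adjusted over the list alone) and 9 than with GDC-0941 (13 and 1), with adjusted p = 0.115 and 0.0549 with an estimated correlation. C3, the central complement protein, differed by 1.14 and 1.24, and Fgb, a fibrinogen chain, by 1.21 against enzastaurin. Socs3, the feedback inhibitor of cytokine signalling, differed by 2.00 and 3.10, and the metallothionein Mt2 by 5.87 and 5.12, with reads that Mt1 may share. S100a9, a neutrophil protein, stood at 33.2 ± 14.2 CPM against 3.07 ± 1.79 and 1.18 ± 0.481. Prtn3, a neutrophil protease, had 96.8 ± 87.6 CPM against 0.253 and 0.586, under about 3 counts per library in the other livers.

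**Figure D4:**
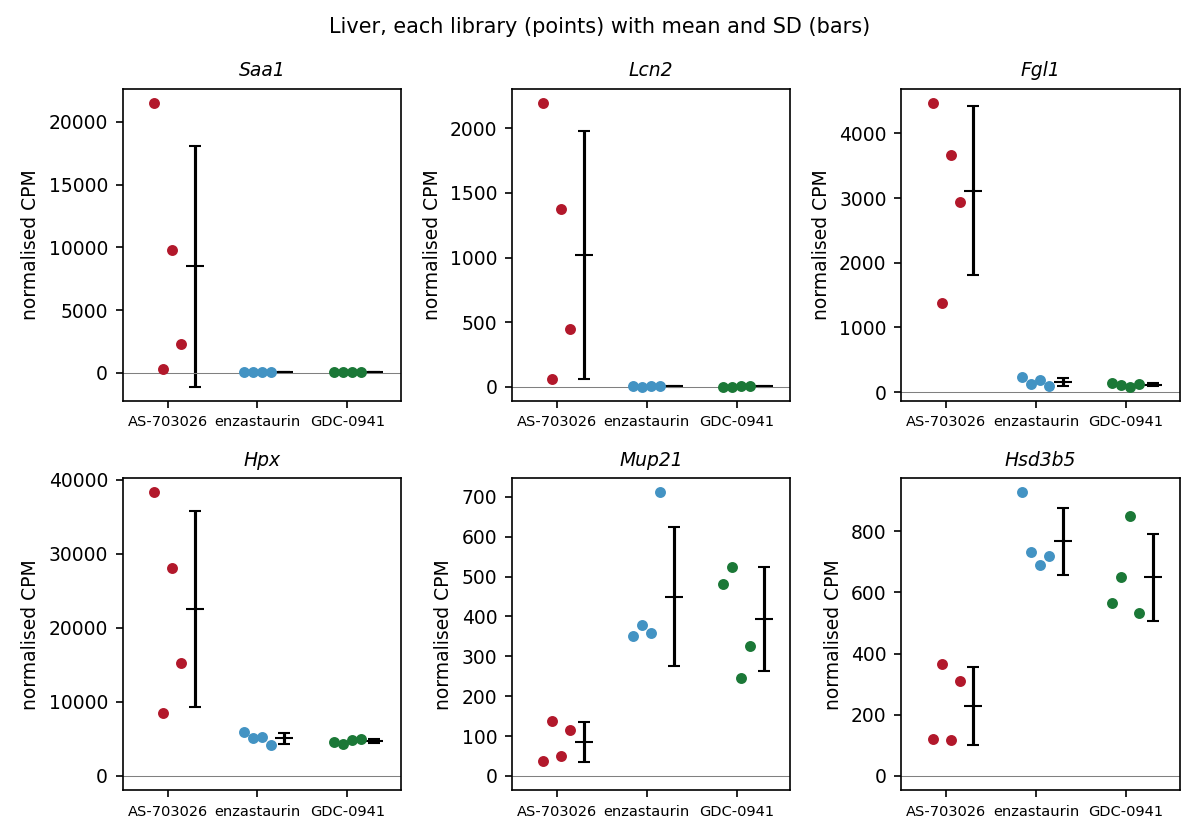
Normalised CPM of 6 genes in the 4 AS-703026, 4 enzastaurin and 4 GDC-0941 liver libraries, 1 point per library, with the mean and SD of each group beside the points. Fgl1 lay between 1384 and 4469 CPM in the AS-703026 livers and at no more than 236 in the others, and Mup21 lay between 37.6 and 139 against 245 or more.

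Some male-biased genes were lower in AS-703026 liver, though the list did not pass. Of 21 measured genes that are male-biased in mouse liver, 9 were lower and 1 higher than with enzastaurin (12 lower and 1 higher adjusted over the list alone), and 4 lower and 1 higher than with GDC-0941 (12 and 1), with medians of -0.89 and -0.81 and adjusted p = 0.0562 and 0.0549 with an estimated correlation. Hsd3b5, a steroid dehydrogenase, stood at 229 ± 128 CPM (SD, n = 4) against 766 ± 108 and 649 ± 142, and Slco1a1 at 357 ± 151 against 724 ± 42.6 and 742 ± 74.8. Mup21, a major urinary protein with close copies in the genome and therefore of uncertain level, differed by -2.43 and -2.24 on the log2 scale. Elovl3, a fatty acid elongase whose annotation overlaps Pitx3, differed by -1.40 from enzastaurin, and Ugt2b1, a glucuronosyltransferase, by -1.17 and -1.10. Slc22a30 stood at 168 ± 21.5 CPM against 343 ± 45.0 and 368 ± 54.2. Cyp8b1 and Cyp7a1, enzymes of bile acid synthesis, were lower by edgeR against 1 compound each, with log2 differences of -1.16 from enzastaurin and -1.20 from GDC-0941. Of 19 bile acid and cholesterol transport genes, 2 were lower than with enzastaurin (4 adjusted over the list alone) and 1 than with GDC-0941 (6), with adjusted p = 0.186 and 0.144 with an estimated correlation. Of 28 urea cycle and amino acid catabolism genes, 3 and 2 were lower (5 lower, and 6 lower with 1 higher, adjusted over the list alone; adjusted p = 0.186 and 0.144), among them Otc, the ornithine transcarbamylase, at -0.52 and -0.63 and Tdo2, the tryptophan dioxygenase, at -0.62 and -0.66.

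Against GDC-0941, 6 of 24 sterol biosynthesis genes were higher with AS-703026 (12 adjusted over the list alone, median 0.55, adjusted p = 0.144 with an estimated correlation), and 1 was higher against enzastaurin (1 adjusted over the list alone, median 0.07, adjusted p = 0.800). Among the 6 were Hmgcs1, the cytosolic HMG-CoA synthase, at 0.86 and Pmvk, the phosphomevalonate kinase, at 0.96. Of 31 PPAR alpha and fatty acid oxidation genes 5 were lower than with GDC-0941 (11 adjusted over the list alone, median -0.31, adjusted p = 0.176) and 1 than with enzastaurin (6, median -0.15, 0.676). Lower than with GDC-0941 were Acadm, an acyl-CoA dehydrogenase, at -0.55, and G0s2, an inhibitor of fat breakdown, at -2.74 (-1.54 against enzastaurin). All 5 erythroid genes were higher than with enzastaurin (5 adjusted over the list alone, median 1.40, adjusted p = 0.0708 with an estimated correlation) and 2 than with GDC-0941 (5, 0.144).

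Counts of calls in liver were 183 higher and 98 lower for AS-703026 against enzastaurin and 194 higher and 112 lower against GDC-0941 by edgeR, among 9490 genes (1538 and 1527 at an unadjusted p under 0.05). Without AS-703026 replicate 3 the totals were 124 and 148, without replicate 1 they were 172 and 156, and 145 without enzastaurin replicate 4 and 193 without GDC-0941 replicate 4. With the satellite-like share as a covariate, which was higher in the AS-703026 livers, the totals were 1 and 22. Fgl1 then differed by 4.73 ± 0.61 and 5.08 ± 0.47 (edgeR adjusted p of 0.0203 and 4.39e-04). Camera called 0 of 53 lists in both (9 and 14 at an unadjusted p under 0.05, 17 and 21 with a preset correlation, 10 and 16 by fry). The F test among the 3 liver groups called 304 genes by edgeR, and 169 or 125 without AS-703026 replicate 1 or 3.

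Enzastaurin and GDC-0941 livers differed in 0 genes by edgeR (762 at an unadjusted p under 0.05), against 18 by DESeq2 and 0 by limma voom, the lowest edgeR adjusted p being 0.226. Bhlhe40, a clock-related repressor, was among the leading genes, which did not pass, and stood at 14.6 ± 3.01 against 35.0 ± 10.3 CPM (SD, n = 4 each). Without GDC-0941 replicate 1 there was 1 call. Camera called 0 of 53 lists (4 at an unadjusted p under 0.05, 15 with a preset correlation, 0 by fry).

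The effects of the 3 compounds given in both tissues differed between kidney and liver for 20 of 12262 genes by edgeR (1228 at an unadjusted p under 0.05). Il13ra1, a receptor chain for interleukin-13, was 49.4 ± 10.8 CPM (SD, n = 4) in AS-703026 liver against 19.5 ± 3.46 with enzastaurin, while in kidney it was 27.5 ± 4.72 against 48.5 ± 12.1 (edgeR adjusted p for the interaction 3.04e-04). Slc41a2, a magnesium transporter, was 129 ± 40.8 CPM against 39.7 ± 5.23 and 26.3 ± 4.00 in liver, and 34.1 ± 12.8, 36.5 ± 4.84 and 37.0 ± 6.83 in kidney (0.00116). Dnajc12, a co-chaperone, was 210 ± 160 against 25.6 ± 6.58 and 23.3 ± 5.11 in liver, and 323 ± 73.1, 391 ± 84.9 and 527 ± 31.8 in kidney (0.00246). Mt1 was 2361 ± 1743 CPM against 79.7 ± 39.4 and 163 ± 159 in liver, and 151 ± 20.5, 192 ± 47.2 and 176 ± 74.5 in kidney (0.00899). The count was 11 without kidney AS-703026 replicate 2, 38 without kidney replicate 1 and 13 without liver AS-703026 replicate 3, and 0 without the kidney libraries of high satellite-like share.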

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

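Of the tests in this part, only the comparison of the 2 parts of the file order had its measure written down before the result it bears on was seen, and the interaction test was planned. The other tests, the regroupings of libraries included, were chosen after the results were seen. A library was singled out when its gap to the nearest other library of its group exceeded Dixon's 95% critical value as a share of the group's range, which chance does in about 1 in 20 groups. This happened in 46 of 283 groups tested, with 19 in AZD8055 kidney replicate 4 and 8 in AS-703026 kidney replicate 4. Most groups were of genes named for their calls in these same data, and some such calls rested on a single library. The 14.2 flags expected by chance are therefore no measure for the 46.

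Adipocyte transcripts in AZD8055 kidney were the clearest case. As shares of the group's range, the gap of replicate 4 was 0.999 for Ucp1, 0.997 for Fabp4, 0.999 for Thrsp, 0.998 for Fasn, 0.987 for Cebpa, 0.996 for Lipe, 0.996 for Pdk4, 0.972 for Hadha, 0.924 for Sucla2, 0.869 for Uqcrc2, 0.912 for Ndufb9, 0.842 for Mrpl10, 0.973 for Map1lc3a, 0.967 for Eif4ebp1, 0.998 for Vim, 0.880 for Neat1, 0.996 for Cidea, 0.999 for Cfd and 0.998 for Car3. Adipose tissue taken with 1 kidney is a candidate explanation, since the median log2 change of the adipocyte list was -0.0205 without replicate 4 and its most abundant genes stood together there, Car3 at 24127, Fabp4 at 17334 and Cfd at 7144 CPM. An effect of the compound on kidney cells is argued against by the other AZD8055 libraries, the lowest of which had a list median of -0.138 against 8.46 in replicate 4. Of 3 kidney markers, Kap was 9723 CPM there and at least 27762 in the other kidney libraries, Slc34a1 2097 against at least 2562, and Umod 737, inside the range of the others (586 to 4602). Whether the fat was around or within the kidney cannot be read from the counts, and a real change in that mouse stays open.

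Genes lower than control under several compounds were highest in 4 of the 6 controls. For the 28 genes lower under 2 or more compounds, the median differences of controls 1 to 6 from the mean of the compound libraries were 0.84, 0.19, 0.98, 1.10, 1.36 and 0.27, a measure chosen after the first was seen. A difference between the 2 parts of the file order is argued against only for the compounds with libraries in both parts. Among compound libraries, within compound, the earlier part minus the later was -0.130 (quartiles -0.223 to 0.105), where the genes' own change had a median size of 0.832. All AZD8055 libraries lie in the earlier part and add nothing to this difference. The earlier libraries of the other compounds all come before controls 3, 4 and 5 in the file. A difference limited to the stretch around those controls was therefore not tested. A library property shared by controls 1, 3, 4 and 5 cannot be told apart from an effect of the compounds, because controls 2 and 6 lay low (-0.660 for the higher of them against the other 5 controls) but control 1 lay at -0.03, between the others. A shared response to eating a compound therefore stays open, as does handling of 4 control kidneys, in which the nuclear RNAs Malat1 and Neat1 were at 1159 to 2101 and 523 to 1399 CPM against medians of 446 and 231 in compound libraries.

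Acute phase genes in AS-703026 liver moved with a higher share of satellite-like counts. With that share as a covariate the list's median log2 change over enzastaurin was 2.04 against 2.14 without it, and over GDC-0941 1.90 against 2.26. The share was 0.857% or more in the AS-703026 livers and 0.645% or less in the others. As the groups do not overlap in it, the covariate cannot separate this background from the compound, and no conclusion is drawn. Over enzastaurin the median standard error grew from 0.339 to 0.604 and the members past 0.05 fell from 22 to 0, so these calls ended because the error grew, and over GDC-0941 they fell from 22 to 6. The list's summed level was 84800 CPM higher than with enzastaurin. Neutrophils are argued against as the direct source of that sum, since S100a8 and S100a9, abundant in these cells, reached 46.0 CPM, equal to 0.0543% of it. Prtn3 reached 96.8 CPM. As the sum is weighted to abundant genes, it does not show whether neutrophils entered these livers, and other leukocytes were not tested. An inflammatory response of hepatocytes, brought on by the compound or by an infection or injury of mice in that group, may underlie the higher list, and no test here separates these. Without liver controls, higher levels with AS-703026 cannot be told from lower levels with both other compounds.

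Among AS-703026 kidney libraries, replicate 4 stood highest with gaps of 0.890 of the range for Cryab, 0.975 for Aqp2, 0.856 for Aqp4, 0.951 for Krt18, 0.951 for Ifit3, 0.971 for Sptssb, 0.931 for Gstm2 and 0.919 for Serping1. Zfp697 was highest in replicate 1 (0.857) and Crebzf in replicate 3 (0.859). In control kidneys, Cyp24a1 was highest in replicate 3 (0.637), Gstm2 and Serping1 in replicate 2 (0.746 and 0.703), and Cycs lowest in replicate 1 (0.642). The satellite-like share was highest in replicate 1 of enzastaurin (0.995), replicate 1 of KU0063794 (0.982) and replicate 4 of ascorbyl-palmitate (0.967), which also led in genes detected (0.976) and in Cpsf6 (0.842). KU0063794 replicate 3 led in Khdc4 (0.865) and replicate 1 in Cidea (0.855).

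In liver, enzastaurin replicate 4 was highest for Mup21 (0.919) and replicate 1 for Otc (0.885), AS-703026 replicate 4 was highest for Hbb-bt (0.916), replicate 3 lowest for G0s2 (0.885) and replicate 1 lowest for Acadm (0.875), and GDC-0941 replicate 3 was lowest for Prtn3 (0.890), at 0 counts. Genes whose compound effects differed between kidney and liver in edgeR's interaction test were Il13ra1 (adjusted p 3.04e-04), Atp11a (0.00108), Slc41a2 (0.00116), Tmem176a (0.00137), Dnajc12 (0.00246), Steap2 (0.00468), Tmem176b and Mt1 (0.00899 each) and Mt2 (0.0101). Tmem176a and Tmem176b overlap on opposite strands and Mt1 and Mt2 are close copies, so these are not separate findings.

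Regroupings of the libraries asked whether as many calls arise by chance. The splits as large include the real grouping. In kidney their share was under 0.05 for AS-703026 (108 calls, 2 of 50 splits as large, highest other 150) and AZD8055 (640, 1 of 50, 304). In liver it was under 0.05 for AS-703026 against enzastaurin (281, 1 of 35, 20) and GDC-0941 (306, 1 of 35, 2). The same held for the liver F test (304, 1 of 50, 68) and the interaction (20, 2 of 50, 56). These shares were not adjusted for the number of results regrouped. Chance cannot be excluded for ascorbyl-palmitate (5, 6 of 50, 599) or KU0063794 (5, 5 of 50, 591). Nor can it be for AZD8055 against KU0063794 (74, 12 of 35, 191) or the kidney F test (294, 3 of 50, 347). Where the real count is 0, every split is as large by definition, so the share tests nothing. This was the case for enzastaurin in kidney (0, 50 of 50, 52) and enzastaurin against GDC-0941 in liver (0, 35 of 35, 5). For GDC-0941 in kidney (16, 2 of 50, 64) the share was under 0.05 too, but the count was 0 without control 1, 3, 4 or 5. The count of AS-703026 in kidney was likewise 0 without its replicate 4, control 4 or control 5, and that of AZD8055 was 25 without its replicate 4. A low share therefore does not tie these kidney calls to the compounds. Splits that call several times the real count numbered 5 for ascorbyl-palmitate, 3 for KU0063794 and 1 for GDC-0941 in kidney. Where the real count was 0, splits with any call numbered 4 for enzastaurin in kidney and 5 for enzastaurin against GDC-0941 in liver. What gave rise to them was not tested.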

How the results depend on the processing

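Tests with the satellite-like share, without the satellite-rich kidney libraries or with the part of the file order were chosen after the results were seen, as were leaving out AZD8055 replicate 4 for comparisons that do not include it and leaving out single libraries for the similarity of compounds; the others were planned. Of 2756 alternative values of 151 gene results, 1980 kept their direction and their side of the threshold, 743 lost a call, 27 gained one and 6 reversed. The reversed values were Sptssb with AS-703026 without satellite-rich libraries (-0.72), Pdk4 with AZD8055 by voom (-0.94), and 4 results without AZD8055 replicate 4, where leaving out 1 library gave -0.13 to 7.80 for Thrsp, -0.36 to 6.22 for Fasn and -1.34 to 5.54 for Pdk4, and -0.30 to 6.24 for Fasn against KU0063794. Where an alternative moved a result the cause was not tested, except that an unfiltered fit tests more genes, a fit of 2 groups has fewer libraries, and leaving out the 11 kidney libraries with 5% or more satellite-like counts leaves 1 of AS-703026, assumed to vary like the others, and replicates 3 and 4 of AZD8055. Depth, from 863605 counts in kidney and 1084591 in liver, limits what low genes can show.

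Calls are given as total (higher/lower). AS-703026 in kidney, 108 (53/55), gave 258 (111/147) by DESeq2, 296 (192/104) without a filter, 188 (37/151) by voom, 20 (7/13) with the satellite covariate, 1 (1/0) without satellite-rich libraries and 1 (0/1) with the file order covariate. With the satellite and file order covariates the median log2 change of its higher genes was 1.79 or more against 1.96, and of its lower genes -0.89 and -0.88 against -0.90. Under these covariates calls were thus lost with little change in size. Without satellite-rich libraries, where 1 AS-703026 library remained, the medians were 0.87 and -0.78. Ascorbyl-palmitate, 5 (0/5), gave 147 (50/97), 155 (88/67), 307 (105/202), 0, 0 and 0 in that order, and 0 in a fit of 2 groups. AZD8055, 640 (442/198), gave 235 (111/124) by voom, 0 in a fit of 2 groups, 1219 (855/364) without satellite-rich libraries and 25 without replicate 4. Enzastaurin, 0 by edgeR with 915 genes at an unadjusted p under 0.05, gave 27 (2/25) by DESeq2, 57 (34/23) without a filter and 154 (27/127) by voom. GDC-0941, 16 (2/14), gave 185 (59/126) by DESeq2, 7 (1/6) with RLE, 70 (22/48) without a filter, 100 (22/78) by voom, 1 (0/1) in a fit of 2 groups, and 0, 0 and 0 with the satellite covariate, without satellite-rich libraries and with the file order covariate. KU0063794, 5 (0/5), gave 61 (4/57), 49 (3/46), 342 (106/236), 0, 0, 0 and 0 by DESeq2, no filter, voom, 2 groups and those 3. AZD8055 against KU0063794, 74 (74/0), gave 23 (21/2), 401 (378/23), 0, 0, 0, 597 (529/68) and 0 in the same order. The kidney F test, 294, gave 525 by DESeq2, 1196 without a filter, 188 by voom and 57 with the file order covariate.

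In liver, AS-703026 against enzastaurin, 281 (183/98), gave 673 (384/289) without a filter, 186 (133/53) in a fit of 2 groups and 1 (1/0) with the satellite covariate. Against GDC-0941, 306 (194/112), it gave 769 (426/343) without a filter and 22 (19/3) with the satellite covariate. Enzastaurin against GDC-0941, 0 by edgeR with 762 at an unadjusted p under 0.05, gave 18 (7/11) by DESeq2, 207 (113/94) without a filter and 15 (5/10) in a fit of 2 groups. The liver F test, 304, gave 498 by DESeq2, 940 without a filter and 9 with the satellite covariate. The interaction, 20, gave 131 by DESeq2, 484 without a filter, 31 with the satellite covariate, 0 without satellite-rich libraries and 49 with the file order covariate.

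Leaving out 1 library gave 0 to 339 calls for AS-703026 in kidney (0 without control 4, 339 without AZD8055 replicate 4), 0 to 130 for ascorbyl-palmitate, 25 to 842 for AZD8055, 0 to 60 for enzastaurin, 0 to 159 for GDC-0941, 0 to 73 for KU0063794, 0 to 296 for AZD8055 against KU0063794, 140 to 398 for the kidney F test, 124 to 359 and 148 to 456 for AS-703026 in liver against enzastaurin and GDC-0941, 0 to 1 between those 2, 125 to 384 for the liver F test and 11 to 38 for the interaction. The similarity of compound responses, 0.336, was 0.263 to 0.444 without 1 library, 0.0939 with the controls split between compounds, 0.526 over genes of at least 20 CPM, 0.515 with the satellite covariate, 0.420 without satellite-rich libraries and 0.310 with the file order covariate.

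Of the gene lists, 0 passed by camera with an estimated correlation in the comparisons of 2 groups. With a preset correlation 23, 14, 18, 11, 9, 10 and 21 passed for kidney comparisons in the order given above, the last AZD8055 against KU0063794, and 17, 21 and 15 in liver (AS-703026 against enzastaurin and GDC-0941, and between those). By fry 2 passed for AZD8055 and 10 and 16 for AS-703026 in liver, and 0 in the other comparisons. At an unadjusted p under 0.05 camera had 8, 1, 4, 3, 2, 0 and 3 in kidney and 9, 14 and 4 in liver.

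The labels share replicate numbers across groups, but do not say whether these pair the libraries. Median correlations of same-numbered deviations were -0.0228 in kidney (25 of 84 over 0.1), -0.0286 in liver (1 of 12) and 0.0205 across tissues (2 of 12). By best correlation, 8 of 30 kidney and 2 of 12 liver libraries matched their own number. Low correlations cannot show that libraries are unpaired, so pairing stays open. With the replicate block the calls were 0 for AS-703026, 15 (0/15) for ascorbyl-palmitate, 27 (3/24) for AZD8055, 2 (0/2) for enzastaurin, 0 for GDC-0941, 11 (0/11) for KU0063794, 0 for AZD8055 against KU0063794, 9 for the kidney F test and 11 for the interaction, and 0 lists passed.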

Other observations

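Tests of single libraries against the control mean in this part were chosen after the results were seen. Values of several lists that did not pass follow, picked then too, with an adjustment over each list alone beside the one over all genes. Between enzastaurin and GDC-0941 livers, 0 of 17 circadian clock genes passed by edgeR, but adjusted over the list alone 9 were lower and 3 higher with enzastaurin, with a median log2 difference of -0.79 (adjusted p = 0.440 with an estimated correlation). Bhlhe40 of that list differed by -1.28. Of 24 sterol biosynthesis genes, 0 passed and 6 were higher adjusted over the list alone (median 0.40, adjusted p = 0.440). The time of day at which tissue was taken is not given in the sources used here.

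In kidney, 0 of 11 thick ascending limb genes passed with ascorbyl-palmitate by edgeR, and 7 were higher adjusted over the list alone, with a median of 1.25 (adjusted p = 0.539 with an estimated correlation). With AS-703026, 0 of 7 smooth muscle genes passed and 5 were higher adjusted over the list alone (median 0.99, adjusted p = 0.290), and 0 of 6 erythroid genes passed and 4 were higher (median 1.34, 0.290). The thin limb and inner medulla list stood 3.69 above the control mean in AS-703026 replicate 4 and at 0.31, 0.82 and 0.13 in the other 3 libraries of that compound. Hepatocyte genes stood 4.24 above the control mean in enzastaurin replicate 1 and 3.45 above it in AZD8055 replicate 4, with 0.98, -0.37 and 0.06 in enzastaurin replicates 2 to 4 and 0.44, 0.53 and 0.30 in AZD8055 replicates 1 to 3. In AS-703026 liver, 4 of 14 glucocorticoid-responsive genes were higher than with enzastaurin (7 higher and 1 lower adjusted over the list alone, median 0.55, adjusted p = 0.186), though Lcn2, Mt1 and Mt2 of this list are also acute phase genes. ERK feedback genes in liver had medians of -0.30 and -0.38 against enzastaurin and GDC-0941 over 7 measured members (adjusted p = 0.800 and 0.620), with 0 past 0.05.

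The higher and lower genes of AS-703026 kidney differed in how their size changed without replicate 4, though no call in either direction held. A share of medullary tissue larger than in the other kidneys may account for part of the higher genes, whose median log2 change was 1.96 and 0.92 without replicate 4, when the count of calls was 0. The lower genes had a median of -0.90 and of -0.89 without replicate 4. Without replicate 2 or 3 the lower calls went from 55 to 16 and 21, and the higher calls from 53 to 51 and 72. These fits keep all the controls, and the count of calls was also 0 without control 4 or control 5. Of the lower genes, 24 were also lower with AZD8055, which was compared with the same controls. No test here was written to decide between a different piece of kidney and an effect of the compound in the mouse of replicate 4.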
